A study of Mus musculus with 12 samples.

How the data were processed

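Bulk RNA from brain tissue of 12 male B6 mice aged 13 weeks was measured in 3 groups of 4: uninjured mice, mice with a cerebrovascular injury, and injured mice given antibodies against the integrins LFA1 and VLA4 continuously. Per the labels' protocols, the mice were perfused with saline on day 20 after injury, a tissue cube with edges of 3 mm was frozen, and 500 ng of total RNA per library entered a stranded total RNA kit. The labels describe different mice and call each sample a biological replicate.

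The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.8, Trimmomatic 0.39 and the genome build GRCm38. The aligner and the counting program are not given in the sources used here. Per the file headers, the deposited tables give the total and unique count of reads over exons, introns, exon junctions and whole genes. The values in the deposited count columns are whole numbers, and exon reads per library ranged from 13330379 to 16121577. The authors also deposited TPM, which the total exon reads and exon lengths gave back in all 12 libraries, and which a further expression column repeated. The RPKM values, per the file headers scaled to exon length and mapped reads, were used only to read the mapped total of each library. Each table listed the same 25749 genes in the same order, and all 25749 gene identifiers matched GENCODE M21 with the same start and end. Whether counting used the strand is not stated, so overlapping genes cannot be separated with certainty.

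The tests used the total exon reads as deposited, which include reads that match more than 1 place. Genes with low counts were removed with edgeR's filterByExpr by group, which left 14771 genes, and libraries were scaled with TMM factors. One edgeR 4.0.16 quasi-likelihood model in R 4.3.3 held all 12 libraries with group as the only term, leaving 9 residual degrees of freedom. Each pair of groups was tested two-sided with Benjamini-Hochberg adjustment at 0.05. Levels are normalised CPM, counts scaled to the effective library size, given as mean ± SD over 4 libraries, and log2 fold changes carry the standard error (SE). A set of 40 gene lists of brain and blood cell types, regions and pathways was fixed before the data were examined, and 764 of its 770 genes were in the tables. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 40 lists and 3 comparisons. The list tests were also computed with a correlation estimated per list. In every list that passed, this gave a larger adjusted p than the preset correlation. It is given where it ended a call and for some lists that kept theirs.

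Named genes followed a rule fixed at the same time. It took the 5 higher and 5 lower genes of largest fold that passed the test, reached 1 CPM on average in the higher group and had no overlap between the libraries of the groups. It added the 2 members of smallest p in each of the 8 lists with the smallest camera p, up to 2 further members by the next smallest p, and the genes of the blocked integrins. Genes with only a clone, predicted or pseudogene name were passed over. Where no library of a group held a read, the fold is a lower bound computed against 3 reads over the group, which covers counting error only. Gene lists of muscle, bone, hypothalamus, habenula and antibody-secreting cells were chosen after seeing the data.

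The alternatives fixed in advance were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma voom, only the compared groups in the model, a replicate block, a robust spread estimate, a test against a fold of 1.2, and each library left out. Alternatives for normalised values alone were not needed. Alternatives chosen after seeing the data were a GC and length trend removed from each library with mgcv 1.9.3, unique reads, a fold of at least 2, both libraries at the ends of the first principal component left out, overlapping genes left out, and the phagocytosis and lysosome list without the genes it shares with the activation list.

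The code was tested on simulated counts drawn from the real means, spreads and library sizes with 200 changed genes among 14771. Each gene was drawn independently, without the GC and length trend of the real libraries. The shares of false calls below may therefore not hold for the real data. In the simulation of injured vs uninjured, 82% of genes changed 1.5-fold and 2% of those changed 1.2-fold were recovered, with 6.16% false calls. For injured with anti-LFA1/VLA4 vs uninjured the shares were 64% at 1.5-fold and 4% at 1.2-fold, with 8.03% false calls. For injured with anti-LFA1/VLA4 vs injured they were 64% and 4%, with 8.51% false calls. When the activation list alone was raised 1.5-fold in simulated counts, the phagocytosis and lysosome list, which shares 8 genes with it, was called in all 3 comparisons. Without those genes, left out after seeing the data, it was not called in any, while 1 other list was called in the simulation of injured with anti-LFA1/VLA4 vs injured.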

Results

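Total RNA of brain tissue was sequenced in 4 uninjured mice, 4 injured mice and 4 injured mice given anti-LFA1/VLA4, antibodies against integrins that leukocytes use to leave the blood. The title of the series concerns myeloid cells in damage and repair after cerebrovascular injury. Exon reads per library averaged 15487500 ± 270943 (SD, n = 4) in uninjured, 15920500 ± 286897 in injured and 13706800 ± 268175 in antibody-treated mice, so depth was lowest in the last group. Reads from the mitochondrial genome made up 11.4 ± 0.761% (SD, n = 4) of exon reads in uninjured, 6.84 ± 1.51% in injured and 10.04 ± 0.945% in antibody-treated libraries. The first principal component held 38.3% of the variance and the second 25.9%, with uninjured replicate 1 and antibody-treated replicate 4 at the ends of the first. Among genes with at least 200 reads in a group, the median variance between libraries was 2.80 times counting noise in uninjured, 3.20 in injured and 5.02 in antibody-treated mice. With each library's GC and length trend removed it was 1.53, 1.72 and 2.29.

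The first comparison asked what differed in injured tissue 20 days after injury. Transcripts of activated microglia and macrophages, antigen presentation, complement, reactive astrocytes and collagen matrix were higher in injured than in uninjured mice. Spp1, the matrix protein osteopontin, rose from 22.1 ± 1.59 to 62.5 ± 5.12 CPM (SD, n = 4; 2.83-fold, SE of the log2 fold change 0.08, edgeR adjusted p = 3.35e-07). In the microglia and macrophage activation list 20 of 26 tested members were higher and 1 was lower (camera adjusted p = 2.59e-12), or 22 and 1 adjusted over the list alone. With an estimated correlation the camera adjusted p was only 0.0328 for this list and for MHC class II. It was 0.0209 for complement and for fibrotic matrix, and 0.0200 for thalamus. Other leading members were Gpnmb (log2 fold change 0.94), Itgax (1.81) and Cst7 (1.86).

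MHC class II genes, which present peptides to T helper cells, were higher in 6 of 9 tested members (camera adjusted p = 2.90e-07). H2-Aa rose by a log2 fold change of 1.59 (SE 0.11), Cd74, the invariant chain, by 1.55 (SE 0.13), H2-Ab1 by 1.56 and H2-Eb1 by 1.38. MHC class I genes were higher in 12 of 15 members, led by H2-D1 (0.85) and H2-Q6 (1.05). That list had a camera adjusted p = 1.42e-08 and an adjusted p = 0.146 with an estimated correlation. Among complement genes 9 of 16 were higher (camera adjusted p = 1.38e-06), with C4b at 1.25 (SE 0.06) and C3 at 0.99 (SE 0.08). Reactive astrocyte genes were higher in 10 of 25 members (camera adjusted p = 1.38e-06), including the protease inhibitor Serpina3n (log2 fold change 1.18, SE 0.06) and Gfap, the astrocyte filament protein (1.10, SE 0.06). In the fibroblast and fibrotic matrix list 16 of 28 members were higher and 1 was lower (camera adjusted p = 1.57e-06), and Col1a1, a chain of type I collagen, rose by 1.09 (SE 0.07). Type I interferon response genes were higher in 8 of 25 members (camera adjusted p = 9.29e-05), with Oasl2 at 0.74. The phagocytosis and lysosome list had 16 of 30 members higher and 1 lower, with an adjusted p = 5.88e-06 by camera and an adjusted p = 0.0561 with an estimated correlation. Of its 22 members outside the activation list 10 were higher and 1 lower (camera adjusted p = 0.00335, adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, higher members numbered 9 for MHC class II, 14 for MHC class I, 11 for complement, 10 for reactive astrocytes, 18 for fibrotic matrix with 2 lower, 12 for interferon response and 17 for phagocytosis with 1 lower. Spp1 and Cd74 overlap another annotated gene, so part of their reads cannot be assigned with certainty.

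Genes of nerve cell activity and of brain regions also differed. Immediate early genes, which respond quickly to nerve cell activity, were higher in 12 of 20 members and lower in 4 (camera adjusted p = 2.64e-05), with Arc at 0.89 (SE 0.05) and Btg2 at 0.89 (SE 0.06). Thalamic markers were higher in 10 of 15 members (camera adjusted p = 4.92e-08). Prkcd rose from 32.7 ± 2.18 to 62.6 ± 2.48 CPM (SD, n = 4) and Tcf7l2 rose by a log2 fold change of 0.98. Striatal markers were lower in 7 of 17 members and higher in none (camera adjusted p = 4.88e-07). Drd1, the dopamine D1 receptor, fell by 0.55 on the log2 scale. Choroid plexus and ependyma genes were lower in 8 of 20 members and higher in 1 (camera adjusted p = 0.000542). Mitochondrial genome transcripts were lower in 12 of 13 members (camera adjusted p = 1.97e-08, adjusted p = 0.159 with an estimated correlation), with mt-Nd4 at -1.08 and mt-Cytb at -0.73. Adjusted over the list alone, 12 immediate early genes were higher and 4 lower, 12 thalamic genes higher and 1 lower, 9 striatal genes lower, 1 choroid plexus gene higher and 9 lower, and 13 mitochondrial genes lower.

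Among the other lists, meningeal genes were higher in 8 of 14 members in injured mice (camera adjusted p = 7.34e-05). Basement membrane genes were higher in 4 of 18 (camera adjusted p = 0.0221, adjusted p = 0.507 with an estimated correlation). Ribosomal protein genes had 1 of 30 members higher and a camera adjusted p = 0.00120, with an adjusted p = 0.602 with an estimated correlation. Excitatory neuron genes were lower in 6 of 19 and higher in 2 (camera adjusted p = 0.0484, adjusted p = 0.448 with an estimated correlation). Oligodendrocyte and myelin genes were lower in 9 of 22 and higher in 2 (camera adjusted p = 0.0417), and the list lost its call in 8 of 21 alternatives, with an adjusted p = 0.336 with an estimated correlation. The excitatory neuron list lost its call in 13 of 21 alternatives and the basement membrane list in 5 of 21. Monocyte and infiltrating macrophage genes had 5 of 16 members higher and 1 lower without passing as a list (camera adjusted p = 0.0881), and chemokine and cytokine genes 3 of 15 (camera adjusted p = 0.0868). Neutrophil genes (camera adjusted p = 0.173), red blood cell genes (0.668), T and NK lymphocyte genes (0.985), B and plasma cell genes (0.520), brain endothelium (0.233), angiogenesis (0.424), leukocyte adhesion (0.588), cell cycle (0.0927) and axon growth (0.452) did not pass either. Only 4 of 27 T and NK genes and 5 of 14 B and plasma cell genes passed the count filter. Most lymphocyte markers were thus not tested, in any comparison. With p adjusted over the list alone, 10 meningeal and 4 basement membrane genes were higher, and 2 excitatory neuron genes were higher and 8 lower.

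By fold size, the largest rises among named genes with unique reads were in transcription factor genes at low levels. Pou4f1 rose from 0.116 ± 0.114 to 1.13 ± 0.204 CPM (SD, n = 4), Gata3 by a log2 fold change of 2.91 and Gbx2 by 2.10. Pou4f1 is also a marker in the habenula list and Gbx2 in the thalamus list. For both, an effect of injury cannot be told apart from other proportions of brain regions in the cubes. Fam205a2 (7.40) and Fam205a3 (6.23) share all their reads with near-identical copies and are uncertain. The largest falls were in Capn11 (-2.48), mt-Atp8 (-2.27), Tshr (-1.99), mt-Nd2 (-1.38) and mt-Nd4l (-1.35), of which the 3 mitochondrial genes overlap a neighbour. The call of mt-Atp8 was lost when single libraries were left out, with an edgeR adjusted p = 0.128 without uninjured replicate 1. The call of mt-Nd4l was lost without uninjured replicate 1 (edgeR adjusted p = 0.0574), without injured replicate 4 (0.0595), with the GC and length trend removed (0.0586) and against a fold of 1.2 (0.0986), and that of mt-Nd2 against a fold of 1.2 (0.0588). In all, 1764 of 14771 genes were higher and 1632 lower, of which 103 and 28 changed at least 2-fold. The share of genes without overlap between groups was 30.3%, against 2.86% by chance. With library size alone, 76.0% of called genes were higher in place of 51.9%, and the median log2 fold change of all genes was 0.11 in place of 0.03. Higher genes numbered 838 without uninjured replicate 1, 953 without uninjured replicate 4, 965 without injured replicate 2, 969 without injured replicate 3 and 685 without injured replicate 4, and 819 with the GC and length trend removed. Lower genes numbered 580 without uninjured replicate 1, 1080 without uninjured replicate 2, 747 without uninjured replicate 4, 780 without injured replicate 2 and 700 without injured replicate 4.

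**Figure D1:**
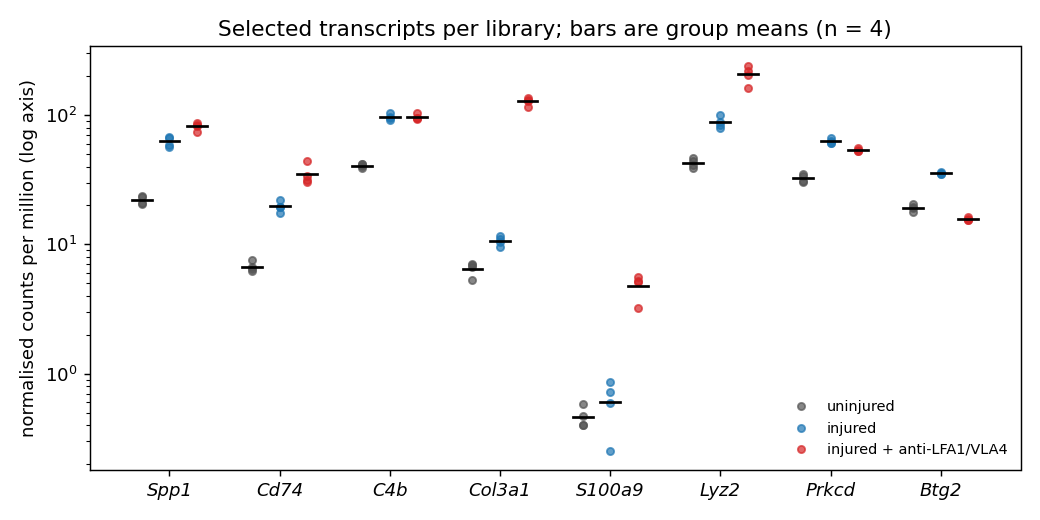
Normalised CPM on a log axis for 8 genes in each library, with points for the 4 libraries of each group and bars for group means. Col3a1 averaged 6.51 CPM in uninjured, 10.6 in injured and 128 in antibody-treated mice.

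The second comparison set injured mice given anti-LFA1/VLA4 against uninjured mice. Collagen genes showed the most significant rises. Col3a1, type III collagen (ENSMUSG00000026043, GRCm38 chromosome 1, 45311538 to 45349706, 57 exons), rose from 6.51 ± 0.814 to 128 ± 8.23 CPM (SD, n = 4; log2 fold change 4.29, SE 0.10, edgeR adjusted p = 1.42e-11). Col1a1 rose by 3.00 (SE 0.07), Col1a2 by 2.51 and Postn, a matrix protein of scars, by 2.58. In the fibroblast and fibrotic matrix list 22 of 28 members were higher (camera adjusted p = 2.34e-26), and 23 were higher and 1 lower adjusted over the list alone. Col3a1 overlaps another annotated gene. Muscle transcripts were also present in these libraries: Ckm, muscle creatine kinase, averaged 13.0 ± 1.79 CPM (SD, n = 4) against 0.0498 ± 0.0641 in uninjured mice.

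Myeloid and inflammatory lists were higher as well. Microglia and macrophage activation genes were higher in 23 of 26 members (camera adjusted p = 9.84e-25), with Gpnmb at 1.69 and Spp1 at 1.89. That list had a camera adjusted p = 0.00827 with an estimated correlation. Phagocytosis and lysosome genes were higher in 22 of 30 (camera adjusted p = 3.10e-18), and in 15 of the 22 outside the activation list (camera adjusted p = 1.28e-12), and Lyz2, lysozyme of myeloid cells, rose by 2.27 (SE 0.12). Interferon response genes were higher in 19 of 25 (camera adjusted p = 2.05e-17), with Oasl2 at 1.30 and Ifi27l2a at 2.86. Reactive astrocyte genes were higher in 17 of 25 (camera adjusted p = 4.39e-17), with Serpina3n at 1.62 and C4b at 1.25. Complement genes were higher in 13 of 16 (camera adjusted p = 1.22e-15), with C3 at 1.90. MHC class I genes were higher in 14 of 15, led by H2-D1 (1.10) and H2-Q6 (1.61), with a camera adjusted p = 8.22e-14 and an adjusted p = 0.0551 with an estimated correlation. MHC class II genes were higher in 7 of 9 (camera adjusted p = 1.25e-10) and thalamic genes in 11 of 15 (camera adjusted p = 7.42e-11), with Prkcd at 0.72 and Tcf7l2 at 1.21. All 6 tested neutrophil genes were higher (camera adjusted p = 1.25e-08), out of 14 listed. The count filter removed the others. It can keep a gene of low level through the group where that gene is high, so this share may partly follow from the filter. Red blood cell genes were higher in 5 of 7 (camera adjusted p = 1.15e-05, adjusted p = 0.147 with an estimated correlation). Genes of synaptic vesicle release were lower in 7 of 22 (camera adjusted p = 1.05e-05, adjusted p = 0.0551 with an estimated correlation). Adjusted over the list alone, higher members numbered 23 for activation, 24 for phagocytosis, 22 for interferon response, 20 for reactive astrocytes, 15 for complement, 14 for MHC class I, 8 for MHC class II, 13 for thalamus, 6 for neutrophils and 5 for red blood cells, and 11 synaptic genes were lower.

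Monocyte and infiltrating macrophage genes were higher in 10 of 16 members (camera adjusted p = 1.22e-08), with Ms4a6c at 1.86 and Ms4a7 at 2.38. Chemokine and cytokine genes were higher in 9 of 15 (camera adjusted p = 1.38e-06), meningeal genes in 9 of 14 (camera adjusted p = 4.99e-08) and choroid plexus genes in 5 of 20 (camera adjusted p = 0.000704). B and plasma cell genes were higher in 3 of 5 (camera adjusted p = 9.77e-05), and iron and heme genes were higher in 8 of 21 and lower in 2 (camera adjusted p = 0.00441). Genes of excitatory neurons were lower in 6 of 19 and higher in 1 (camera adjusted p = 0.00105, adjusted p = 0.218 with an estimated correlation), and those of upper cortical layers were lower in 3 of 15 (camera adjusted p = 0.000227, adjusted p = 0.172 with an estimated correlation). Oligodendrocyte genes were lower in 3 of 22 (camera adjusted p = 0.00676, adjusted p = 0.224 with an estimated correlation). Leukocyte adhesion genes were higher in 3 of 16 (camera adjusted p = 0.0160, adjusted p = 0.0551 with an estimated correlation) and homeostatic microglia genes in 4 of 14 (camera adjusted p = 0.0378, adjusted p = 0.243 with an estimated correlation). Ribosomal protein genes (camera adjusted p = 2.90e-05, adjusted p = 0.507 with an estimated correlation) and striatal genes (camera adjusted p = 0.0469, adjusted p = 0.247 with an estimated correlation) passed with the preset correlation and not with an estimated one. T and NK lymphocyte genes (camera adjusted p = 0.233, 4 of 27 tested), immediate early genes (0.2499), mitochondrial genome transcripts (0.0848), angiogenesis (0.0812), brain endothelium (0.713), cell cycle (0.611) and axon growth (0.945) did not pass. Higher members adjusted over the list alone numbered 11 for monocytes, 11 for chemokines with 1 lower, 11 for meninges, 8 for choroid plexus, 3 for B and plasma cells and 8 for iron and heme with 2 lower. Ms4a6c overlaps another annotated gene.

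Immunoglobulin transcripts separated these libraries from the others. Igkv17-121, a variable segment of the kappa light chain, had 216 reads over the 4 antibody-treated libraries and 0 in uninjured and injured mice, at least 78.4-fold higher than in uninjured mice. Ighv1-52 had 132 reads and was at least 47.9-fold higher, and Ighg3 at least 33.0-fold. Bglap, from the bone list, was at least 35.9-fold higher, with 42.1% of its reads unique. It did not separate these libraries, with 22 reads in injured mice. There it was also higher than in uninjured mice (log2 fold change 5.37, edgeR adjusted p = 0.0359). Reads of variable segments were 81.9% unique for Igkv17-121 and 68.9% for Ighv1-52, so their assignment is uncertain. The lower genes of largest fold were Tshr (-1.42), Pkdrej (-1.10), Polq (-1.01), Tdrd5 (-0.98) and Cep128 (-0.94). The calls of Tshr (edgeR adjusted p = 0.0939 without antibody-treated replicate 1), Polq (0.106 without uninjured replicate 1) and Tdrd5 (0.131 without uninjured replicate 1) were lost when these and further single libraries were left out. In all, 931 genes were higher and 476 lower, 314 and 9 of them at least 2-fold. Leaving out antibody-treated replicate 3 gave 2054 higher and 1915 lower, and removing the GC and length trend gave 2013 lower. Lower genes numbered 220, 236 and 231 without uninjured replicates 1, 2 and 4, and 213, 248 and 260 without antibody-treated replicates 1, 2 and 4. With library size alone, 86.3% of called genes were higher in place of 66.2%. One regrouping of these 8 libraries that mixed the groups gave 4048 calls, more than the 1407 of the real grouping.

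The third comparison set injured tissue with the antibodies against injured tissue without them. Fibrotic matrix, neutrophil, monocyte and interferon genes were higher with the antibodies, and immediate early genes were lower. The antibody-treated libraries also held more muscle, hypothalamic, red blood cell and immunoglobulin transcripts. In this and the second comparison, such transcripts may come with others of the same tissue, and which lists this touches was not tested. For matrix, neutrophil, monocyte, plasma cell and the other lists, an effect of treatment cannot be told apart from other tissue, other brain regions or blood in the cubes. Col3a1 rose by a log2 fold change of 3.59 (SE 0.09, edgeR adjusted p = 7.00e-11) and Col1a1 by 1.91. Of 28 matrix genes 19 were higher and 2 lower (camera adjusted p = 1.71e-12, adjusted p = 0.00493 with an estimated correlation). Beside them, Ckm had 715 reads with the antibodies and 1 in injured mice. Neutrophil genes were higher in 5 of the 6 tested (camera adjusted p = 1.98e-05), with S100a9 at 2.94 (SE 0.26) and S100a8 at 3.05 (SE 0.34), subunits of calprotectin. Here too 14 genes were listed, and the share may partly follow from the count filter. Monocyte and infiltrating macrophage genes were higher in 8 of 16 (camera adjusted p = 1.05e-05), with Ms4a6c at 1.14 and Ccr2, a chemokine receptor of monocytes, at 1.74. Red blood cell genes were higher in 5 of 7 (camera adjusted p = 8.79e-05, adjusted p = 0.181 with an estimated correlation).

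Interferon response genes were higher in 16 of 25 (camera adjusted p = 9.68e-08), with Ifit1 at 1.06 and Ifi27l2a at 1.66. Phagocytosis and lysosome genes were higher in 14 of 30 (camera adjusted p = 2.54e-07) and in 12 of the 22 outside the activation list (camera adjusted p = 3.03e-06), with Lyz2 at 1.23 and Gpnmb at 0.74. Microglia and macrophage activation genes were higher in 12 of 26, among them Clec7a (1.22), with a camera adjusted p = 3.02e-06 and an adjusted p = 0.146 with an estimated correlation. Choroid plexus and ependyma genes were higher in 13 of 20 (camera adjusted p = 1.25e-08), with Enpp2 at 0.65 and Sostdc1 at 0.86. Immediate early genes were lower in 11 of 20 and higher in 3 (camera adjusted p = 0.000436). Btg2 fell from 35.6 ± 0.581 to 15.8 ± 0.444 CPM (SD, n = 4), and Arc fell by 0.71 on the log2 scale. Striatal genes were higher in 5 of 17 (camera adjusted p = 0.00405, adjusted p = 0.122 with an estimated correlation). Mitochondrial genome transcripts were higher in 9 of 13 (camera adjusted p = 2.42e-05, adjusted p = 0.276 with an estimated correlation), with mt-Nd3 at 1.39 and mt-Nd6 at 1.04. With the GC and length trend removed the calls of mt-Nd3 (edgeR adjusted p = 0.341), mt-Nd6 (edgeR adjusted p = 0.674) and the list (camera adjusted p = 0.506) were lost. Adjusted over the list alone, 22 matrix genes were higher and 2 lower, 5 neutrophil, 10 monocyte and 5 red blood cell genes higher, 17 interferon genes higher and 1 lower, 16 phagocytosis, 14 activation, 15 choroid plexus, 6 striatal and 11 mitochondrial genes higher, and 4 immediate early genes higher and 11 lower.

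Complement genes were higher in 7 of 16 with the antibodies (camera adjusted p = 2.90e-05), with C3 at 0.91. Reactive astrocyte genes were higher in 11 of 25 and lower in 1 (camera adjusted p = 8.36e-05), led by Lcn2, lipocalin 2, at 1.48. Chemokine and cytokine genes were higher in 6 of 15 and lower in 1 (camera adjusted p = 0.00105), with Ccl8 at 3.05, and B and plasma cell genes in 2 of 5 (camera adjusted p = 0.000633), with Igkc at 5.71. MHC class II genes were higher in 5 of 9 (camera adjusted p = 0.00922, adjusted p = 0.238 with an estimated correlation) and MHC class I genes in 2 of 15 (camera adjusted p = 0.0230, adjusted p = 0.507 with an estimated correlation). Iron and heme genes were higher in 5 of 21 (camera adjusted p = 0.0208, adjusted p = 0.0561 with an estimated correlation). Synaptic genes were lower in 9 of 22 and higher in 2 (camera adjusted p = 0.00409, adjusted p = 0.187 with an estimated correlation). Thalamic genes (camera adjusted p = 0.635), meningeal genes (0.233), basement membrane (0.0589), T and NK lymphocytes (0.423, 4 of 27 tested), leukocyte adhesion (0.0920), angiogenesis (0.452) and cell cycle (0.320) did not pass. When adjusted over the list alone, 10 complement genes were higher, 12 reactive astrocyte genes higher and 1 lower, 9 chemokine genes higher and 1 lower, 3 B and plasma cell genes higher, and 2 synaptic genes higher and 10 lower.

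Among genes of largest fold, Ighg1, an immunoglobulin heavy chain, averaged 20.7 ± 5.58 CPM (SD, n = 4) with the antibodies and 0.106 ± 0.0873 in injured mice, and Actc1, cardiac actin, was at least 25.7-fold higher. Igkv17-121 was at least 85.3-fold and Ighv1-52 at least 52.1-fold higher. Lower genes were Pou4f1 (-1.69), Trpv6 (-1.23), RPS10-NUDT3 (-3.13) and B3gnt2 (-1.19). RPS10-NUDT3 had no unique reads and B3gnt2 10.5%, so both are uncertain. The call of RPS10-NUDT3 was lost with the DESeq2 Wald test (adjusted p = 0.106), without antibody-treated replicate 2 (edgeR adjusted p = 0.0524) and against a fold of 1.2 (0.0523). Those of Pou4f1 (edgeR adjusted p = 0.0724) and Trpv6 (0.0523) were lost against a fold of 1.2. In all, 1612 genes were higher and 1581 lower, 179 and 30 of them at least 2-fold. Without injured replicate 4 the counts were 1053 and 837, and without antibody-treated replicate 2 lower genes numbered 883.

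The antibodies bind LFA1, made of the chains encoded by Itgal and Itgb2, and VLA4, made of those encoded by Itga4 and Itgb1. Itgb2 was higher than in uninjured mice in injured mice (log2 fold change 0.57, edgeR adjusted p = 0.00603, and 0.0916 against a fold of 1.2) and in antibody-treated mice (0.92, edgeR adjusted p = 0.000150). Against injured mice, antibody-treated mice had higher Itgal (0.70, edgeR adjusted p = 0.0387), Itgb2 (0.35, edgeR adjusted p = 0.0352) and Itgb1 (0.24, edgeR adjusted p = 0.0292). Each of these 3 calls was lost under some alternatives, with edgeR adjusted p-values without injured replicate 2 of 0.0967 for Itgal, 0.0954 for Itgb2 and 0.0766 for Itgb1. Itgb1 was lower in injured than in uninjured mice (-0.23, edgeR adjusted p = 0.0350), a call lost in 10 of 26 alternatives, among them library size alone (edgeR adjusted p = 0.122), the GC and length trend removed (0.128) and a test against a fold of 1.2 (0.877). Itga4 passed in no comparison, with 11.5 ± 2.97 CPM (SD, n = 4) in uninjured, 8.58 ± 1.92 in injured and 10.3 ± 3.32 in antibody-treated mice.

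**Figure D2:**
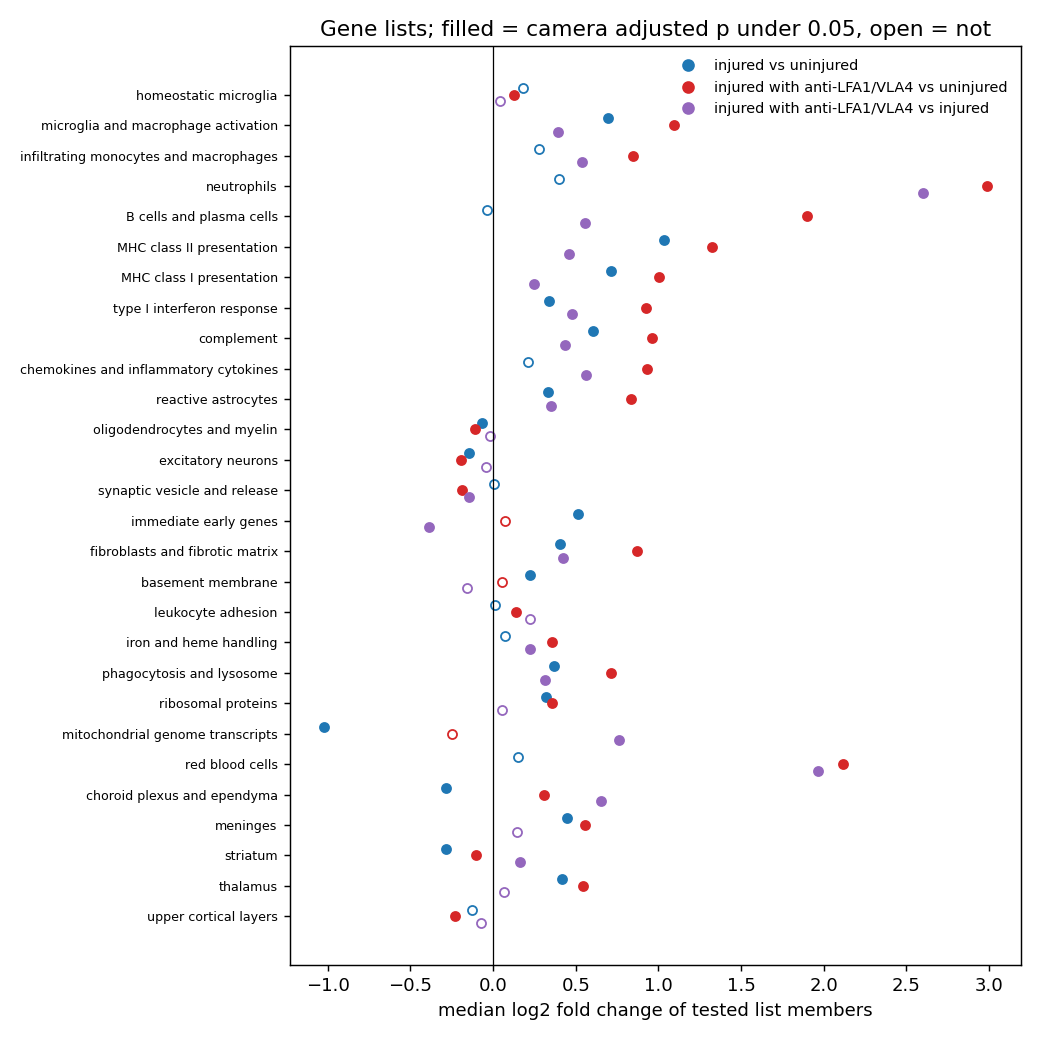
Median log2 fold change of the tested members of each gene list that passed in at least 1 comparison, with 1 colour per comparison and filled points for a camera adjusted p under 0.05. The neutrophil list has medians of 0.40, 2.99 and 2.60 in the first, the second and the third comparison.

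Both injured groups were set against the same uninjured libraries. Of the genes called in both, 392 were higher in both and 110 lower in both, where independent lists would share 111 and 52.6. With the uninjured libraries split between the comparisons, which left 2 in each and lowers the number of calls by itself, the 502 shared calls became 96 to 193. Shared calls numbered 249, 326 and 276 without uninjured replicates 1, 2 and 4, 311, 322 and 327 without injured replicates 2, 3 and 4, and 321 and 1268 without antibody-treated replicates 1 and 3. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.469. In 20 simulations, unchanged groups that shared their controls gave r from 0.430 to 0.539. Shared controls alone thus produce an r of this size, so r cannot tell whether the 2 groups share a response. The covariance was 0.0799 against a mean of 0.0173 and a maximum of 0.0203 in the simulations. Split controls, which the comparisons did not share, gave a median r of 0.353 and a median covariance of 0.0689 (0.0635 to 0.0737). Shared libraries alone therefore do not account for the covariance.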

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

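The tests in this part were chosen after the results were seen, except the regroupings of the libraries without removal of the GC and length trend. Outlying libraries were sought in 141 sets of 4 log2 CPM values of named genes averaging at least 1 CPM, a limit set after seeing that lower values followed library size, and in 21 sets of library quantities. A further 36 sets under that limit were not tested. A total of 8 sets passed the critical value and chance gives 8.1. In uninjured replicate 1, Enpp2 stood at a log2 CPM of 9.42 and Serpina3n at 4.98. RPS10-NUDT3 was at 3.89 in uninjured replicate 3 and Gbx2 at a log2 CPM of -0.0576 in injured replicate 1. In antibody-treated replicate 4, B3gnt2 was at 1.16 and mt-Nd4 at 12.28. In antibody-treated replicate 3, C4b was at 6.70 and S100a9 at 1.74.

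Against uninjured mice, 51 genes were called in opposite directions with and without the antibodies. This is not the full difference between the injured groups, for which the direct test called 3193 genes. In 39 of them the gene was higher in injured and lower in antibody-treated mice, and the direct test between the injured groups called all 51, an outcome that their selection made all but certain.

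The 4 antibody-treated libraries resembled each other in transcripts that usually differ between animals. The same kappa variable segment led in 4 of 4, and the lowest Igkc level was 0.618 of the highest, which argues against spill of reads from a single library. Among heavy chain segments Ighv1-52 led in each library, with 40, 30, 44 and 18 reads in the order of the replicates. Repeat libraries of one RNA would keep variable segments in equal proportions only without bias between libraries. The proportions differed beyond counting noise (chi-square test, p = 0.0389 from 100000 resamples). That test takes reads as independent and p lies near 0.05. It did not remove the length trend, whose Spearman rho ran from -0.634 to 0.677 in these libraries. It therefore cannot decide about repeat libraries or a pool. Separate mice, as the labels state, remain open, since no other repertoires were at hand to say how often mice share a leading segment. If tissue or RNA had been pooled within groups, the SDs and p-values given here would measure spread between libraries and not between mice.

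Transcripts of muscle were higher in antibody-treated libraries. Of 29 tested muscle markers 82.8% were higher than in injured mice, but the list was put together after muscle genes had been seen among the largest folds, so muscle in the tissue cubes stays open. In uninjured mice 9 of these genes averaged at least 1 CPM, with 106 ± 5.26 CPM summed over the list against 290 ± 27.1 with the antibodies (SD, n = 4), and Acta1, skeletal actin, rose from 8.94 to 40.6 CPM. In injured mice without antibodies 10.3% of muscle markers were higher than in uninjured mice, which argues against muscle as the source of their matrix rise. For the antibody-treated group the source of the matrix rise cannot be told apart, because the summed muscle level of the highest library was only 1.24 times that of the lowest.

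Thalamic and striatal markers moved in opposite directions in injured mice. Among called members of these lists 0 went against the others of their region, although 1 thalamic gene was lower when adjusted over the list alone. This restates the pattern, so other proportions of brain regions in the cubes cannot be told apart from other causes. The GC and length trend is argued against, since the striatal list had a camera adjusted p = 2.52e-14 with the trend removed. An effect of the injury on these regions stays open and was not tested.

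Regrouping the libraries gave as many calls in 1 of 35 splits for injured against uninjured mice, the real one, with 3396 calls and 0 in the highest other. For antibody-treated against injured mice it was also 1 of 35, with 3193 calls and 0 in the highest other. For both, 1 of 35 is the smallest share these splits can give, so chance is made less likely and is not excluded. Splits that mix the groups carry the group difference as spread, which lowers their calls by itself. Nor can the splits tell injury or treatment from anything else shared within a group. For antibody-treated against uninjured mice 2 of 35 splits gave as many, with 1407 calls in the real split and 4048 in the highest other, so chance is not excluded for that count. That split exchanged uninjured replicate 3 and antibody-treated replicate 3, which points to a structure of the samples. After this was seen, the splits were repeated with the GC and length trend removed. The real split then led in 1 of 35 in each comparison, with 2200, 3167 and 2756 calls in the order of the report and 0, 570 and 228 in the highest other.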

How the results depend on the processing

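The GC and length trend, unique reads, a fold of at least 2, the ends of the first component, overlapping genes and the shortened phagocytosis list were alternatives chosen only after the results were seen. No named gene that passed the test changed sign under the alternatives run, while Itga4 and Itgb1, uncalled in the second comparison, crossed 0 in 10 cases. Across alternatives 2107 values of named genes kept their side of the threshold and 97 lost it; of list results 2378 kept it, 72 lost it, 69 gained it and 1 reversed. The list of neurotrophic and axon growth genes in antibody-treated against uninjured mice reversed under the fry rotation test (median log2 fold change -0.0380, mean 0.06, limma fry adjusted p = 0.0434, direction up), where camera gave an adjusted p = 0.945; the cause was not tested. An estimated correlation ended 25 list calls. Counts are given as higher and lower in the first, the second and the third comparison. Library size alone gave 3157 and 995 in the first and 201 lower in the second. A test against a fold of 1.2 gave 171 and 40, 445 and 26, 290 and 146, with 101 shared calls, by its stricter construction. Only the compared groups in the model gave 2511 lower in the first, 232 lower in the second, 1058 higher in the third comparison and r = 0.529. DESeq2 gave 883 lower in the second. Replicate numbers did not pair the libraries (same-number correlations from -0.532 to 0.434), and the replicate block gave 213 lower in the second comparison. Leaving out each library gave 685 to 2431 higher and 580 to 2417 lower in the first, 640 to 2054 and 213 to 1915 in the second, 1053 to 1957 and 837 to 1816 in the third, 249 to 1268 shared calls and r from 0.422 to 0.557. The GC and length trend removed gave 819 and 1381 in the first, 1154 and 2013 in the second, 1240 and 1516 in the third, and 985 shared calls. It kept 1184 of 3396 calls with the same sign in the first, 1246 of 1407 in the second and 1466 of 3193 in the third, reversed 3, 0 and 8, and brought the share called higher in the second from 66.2% to 36.4%. A fold of at least 2 gave 103 and 28, 314 and 9, 179 and 30, and 62 shared calls, by its construction. Overlapping genes left out gave 1019 higher in the first, 600 in the second, and 1056 and 1046 in the third, with fewer genes tested. Without uninjured replicate 1 and antibody-treated replicate 4 the second gave 517 and 244, with 280 shared calls and r = 0.381. For the other changes the cause was not tested. Alternatives meant for normalised values alone were not run, since counts were deposited.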

Other observations

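The lists of this paragraph and their tests were chosen only after the values were seen, and they showed further differences in the antibody-treated libraries. Of 9 tested hypothalamic genes 4 were higher than in injured mice, among them Pmch, the precursor of melanin-concentrating hormone, at 10.1 ± 2.12 CPM (SD, n = 4) against 0.387 ± 0.149. Hcrt, the orexin precursor, averaged 2.97 ± 0.942 CPM against 0.0765 ± 0.0590. Of 10 tested genes of antibody-secreting cells 7 were higher, and Jchain, which joins immunoglobulin chains, rose by a log2 fold change of 3.71. Among 10 tested bone genes 3 were higher than in injured mice, but the list did not pass (camera unadjusted p = 0.0750). Its summed level was 151 ± 15.7 CPM (SD, n = 4) against 166 ± 12.8 in injured mice. Before the count filter the hypothalamic list held 18 genes, the antibody-secreting list 14 and the bone list 12. The shares in these lists may partly follow from that filter. Among 12 habenular genes 6 were higher and 1 lower in injured than in uninjured mice, with Gpr151 at 2.10 ± 0.221 against 0.700 ± 0.196 CPM (SD, n = 4), and 2 were lower with the antibodies than without.

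Microglial homeostatic genes in injured mice went both ways, with 5 of 14 higher and 2 lower than in uninjured mice. P2ry12, a purine receptor of resting microglia, was lower in injured mice (log2 fold change -0.77) and higher in antibody-treated than in injured mice (0.55), and it lies inside another gene, Med12l.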
